A study of Mus musculus with 8 samples.

How the data were processed

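RNA sequencing libraries of 4 control and 4 IL-15 treated Tfh samples were analysed from the 1 deposited table, which lists 54532 genes by Ensembl identifier and symbol. Per the labels' protocols, lymph nodes were passed through a filter, cells were sorted and cultured, and libraries followed a protocol published earlier. Per the submitters' processing notes the genome build was mm10. The aligner, the read counter, the annotation release and the normalization tool are not given in the sources used here, nor is the strandedness of the counting, so reads of overlapping and antisense genes cannot be told apart and near-identical gene copies may share reads.

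The deposited values are a signal that the authors made from read counts, although the table is named as counts: every value above 0 was a whole multiple of the value of 1 read in its library (100% of values within 0.001 read), and the median ratio to the geometric mean over genes was 1.093 in all 8 columns, as after division by DESeq2-type size factors. Whole reads were recovered by dividing each column by the value of 1 read. All 8 columns were matched to samples by name. Of the identifiers, 99.8% were found in GENCODE mouse release 21 (mm10), which gave coordinates and the names of 3571 of the 3694 genes listed without a symbol.

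Recovered totals ranged from 514933 to 1311282 reads. Floors of 3 reads per library and intervals of counting cover counting error only, since reads without molecular identifiers are not independent molecules. Ribosomal RNA gene models took 6.20% to 16.9% of reads, most in control 1. None of the 28 pairs of libraries agreed within sampling noise (chi-square per degree of freedom 34.4 to 47.7), so none was treated as a duplicate of another. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

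A count test with edgeR had been planned, but the values are not counts. The main test was therefore limma (version 3.58.1, R 4.3.3) with an intensity trend and robust estimation on log2(value + 1), after edgeR's filterByExpr on the recovered reads, which kept 6180 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The planned quasi-likelihood test of edgeR 4.0.16 was run on the recovered reads instead, a use added after the data were seen. DESeq2 1.42.0 and limma voom on the same reads were chosen beforehand for comparison. Gene lists were tested with camera at a preset correlation of 0.01, for the 29 of 38 lists with at least 5 tested genes. Camera with an estimated correlation and fry were alternatives. None of these 3 tests called a list in the main comparison. Lists called at the preset correlation with library totals alone or without control 3 were not called with an estimated correlation, a check chosen after seeing the data. List totals were compared by exact permutation of the 8 libraries (two-sided). The median and the mean of 7 lists differed in sign. Camera compares a list with all other genes, whose median log2 difference was 0.04, and gave the IL-15 receptor list and the unfolded protein response list a downward direction although their medians and means lay above 0.

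The lists, the named gene rule and most other settings were fixed before the data were examined. The main tests of genes and lists were changed afterwards, as given above. The rule named the 10 genes with the largest change per direction among those past the threshold (0 genes met it), the 2 tested members of each list with the smallest p, 24 fixed genes of IL-15 and Tfh biology whatever their result, and members of other cell type lists for their level. Some genes that the rule names are not reported here. Genes named for the smallest p over all genes, and a list of 39 fibroblast transcripts, were chosen after the data were seen. Further alternatives were other normalizations, filters and pseudocounts, array weights, removal of immunoglobulin, ribosomal protein and mitochondrial genes, a minimum fold, the replicate number in the model, and each library left out in turn. The scripts were tested on simulated counts drawn from the means, depths and dispersions of these libraries, in 10 runs. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.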

Results

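Gene expression was measured by RNA sequencing in 8 libraries of T follicular helper (Tfh) cells, the CD4 T cells that help B cells in germinal centres. The cells were sorted from lymph nodes of mice with the B6 label. Of the libraries, 4 were of control cells and 4 of cells cultured with the cytokine interleukin 15 (IL-15) for 6 h. The design text names kidney transplant recipients as the source. The deposited values were read counts already divided by 1 size factor per library and are called normalized counts here. The reads recovered from them numbered 1311282, 827951, 593843 and 514933 in controls 1 to 4 and 720941, 648906, 961767 and 744302 in IL-15 libraries 1 to 4. Between 8579 and 11374 genes had at least 1 read. Values are given as mean ± SD over n = 4 libraries per group. Each log2 difference is IL-15 minus control on the scale of log2(normalized count + 1). On this scale the difference of a gene with low counts can be larger or smaller than the ratio of its means. It can also differ in sign from the difference of the means. Nlrc5 had -3.26 here and -1.235 in edgeR, and Smarcb1 had 5.85 here and 9.60 in edgeR. Of the 106 tested genes picked by rule or named here, 61 had a group mean that moved more than 1.5 times when 1 library was left out, as had 6 of 38 gene group totals. The difference in means kept its direction with any 1 library left out for 72 of these genes and 16 of the totals. P-values of single genes are from limma. Its adjusted p was 0.978 for Cenpe and Rpl30 and 0.998 for the other tested genes named in the gene groups, except Sel1l.

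The comparison asked which transcripts differ in Tfh cells after 6 h of IL-15. No gene passed the test in either direction. Among 6180 genes tested with limma, 0 were higher and 0 were lower with IL-15 at an adjusted p under 0.05, and the smallest adjusted p was 0.861. The genes closest to the threshold were Usp32, a deubiquitinase (191.8 ± 161.6 in controls, 10.2 ± 8.39 with IL-15), Smarca5, the ISWI chromatin remodelling ATPase (234.9 ± 113.8 and 37.1 ± 15.2), Sel1l, a subunit of the endoplasmic reticulum degradation machinery (549.9 ± 509.6 and 52.2 ± 25.1), and Smarcb1, a subunit of SWI/SNF remodellers. The fixed gene group closest to its threshold was the G2/M cell cycle genes, whose summed normalized count was 1378 ± 185 in controls and 878 ± 168 with IL-15, but this group did not pass its test either.

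At an unadjusted p under 0.05, limma counted 261 genes, 131 higher and 130 lower, where chance alone gives 309. The quasi-likelihood test of edgeR on the recovered reads called 0 genes in each direction (201 at an unadjusted p under 0.05), limma voom called 0 and 0, and DESeq2 called 13 higher and 10 lower. The 4 IL-15 values lay wholly above or below the 4 control values for 155 genes, 2.51% of those tested, where chance gives 2.86%. Libraries of the same group were no more alike than libraries of different groups: across genes, the mean correlation was 0.402 within groups and 0.408 between groups (exact permutation p = 0.914 over 35 splits, the smallest possible being 0.0286).

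The genes with the 5 smallest p-values were picked after their values were seen. Usp32 (chromosome 11, 84984442 to 85140161, mm10) had a log2 difference of -4.45 (95% interval -6.62 to -2.29, limma adjusted p = 0.861). Smarca5 (chromosome 8, 80698507 to 80739497) had -2.60 (-3.94 to -1.25, limma adjusted p = 0.861). Sel1l (chromosome 12, 91806043 to 91849157) had -2.89 (-4.37 to -1.41, limma adjusted p = 0.861), and Dhx30, an RNA helicase (chromosome 9, 110084320 to 110117830), had -3.25 (-5.05 to -1.44, limma adjusted p = 0.934). Smarcb1 (chromosome 10, 75896769 to 75921617) had no reads in any control library and 87.0 ± 91.4 with IL-15 (17.5 to 218.3 in single libraries). Its log2 difference was 5.85 (2.76 to 8.94, limma adjusted p = 0.861). The IL-15 mean was 29.2 times a floor of 3 reads per control library, and 14.5 times without IL-15 library 1. These 2 ratios leave out the spread between libraries. Other settings called some of these: DESeq2 gave Smarcb1 an adjusted p of 1.58e-05, Usp32 0.0123, Sel1l 0.0145 and Smarca5 0.0287, and limma without the filter gave Sel1l 0.0146. Limma without IL-15 library 2 gave Sel1l an adjusted p of 0.0227, Usp32 0.0240 and Dhx30 0.0385, and without control 1 it gave Sel1l 0.00236.

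Genes that respond to cytokines of the common gamma chain family through STAT5 did not pass the test as a group. Of 25 listed, 13 were tested, 8 above and 5 below 0, with a median log2 difference of 0.35 and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.953). Pim1, a serine/threonine kinase, was at 270.7 ± 104.5 in controls and 228.6 ± 66.7 with IL-15 (log2 difference -0.17, 95% interval -1.03 to 0.69). Myc had 0.43 (-2.87 to 3.73) and Bcl2, which blocks apoptosis, 0.92 (-2.06 to 3.89), although its mean was lower with IL-15 (24.6 ± 31.6 and 16.4 ± 0.754) and edgeR gave a log2 difference of -0.59. Tnfrsf4, which encodes the co-stimulatory receptor OX40, was at 20.8 ± 24.5 and 47.4 ± 23.6 (log2 difference 2.73), and Furin, a proprotein convertase, at 23.4 ± 14.1 and 9.07 ± 16.95 (log2 difference -2.80). The feedback inhibitor Cish had reads in 1 library of each group, with 16.5 in IL-15 library 4. Socs2 was at 0.706 ± 0.842 and 2.91 ± 3.03, Socs3 at 10.5 ± 9.89 and 1.13 ± 1.83, and Il2ra, the alpha chain of the IL-2 receptor, at 22.8 ± 30.4 and 1.40 ± 2.17. These 4 genes were below the filter and not tested. The IL-15 receptor and its signalling proteins had a median of 0.12 over 12 tested members (camera adjusted p = 0.953). Il2rb, the beta chain shared by the IL-2 and IL-15 receptors, was at 38.1 ± 43.9 and 56.6 ± 39.9 (log2 difference 0.75), Stat3 at 191.2 ± 80.1 and 108.0 ± 53.4 (log2 difference -0.87), and Pik3r1 at 139.8 ± 169.6 and 55.1 ± 63.7 (log2 difference -1.69). Il15ra had no reads in any of the 8 libraries, which allows up to 1.73 to 3.97 normalized counts per library.

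The Tfh identity group had 17 tested members of 32, 11 above and 6 below 0, with a median log2 difference of 0.43 and 0 past the threshold (camera adjusted p = 0.953). The upward median rested on control 4, the control with the lowest total for this group: without it the median was -0.70 and the control total 962.8, against 779.6 with all controls and 800.7 with IL-15. Without IL-15 library 2 the median was -0.06. Bcl6, the lineage-defining repressor, was at 10.7 ± 6.28 in controls and 8.25 ± 5.22 with IL-15 (log2 difference -0.21). Icos had 1.45 (95% interval -0.83 to 3.73), Maf 2.56 and Il6ra -2.23. The direction of 2 genes depended on the scale: Pdcd1, which encodes PD-1, had 0.56 but means of 26.5 ± 30.8 and 24.8 ± 25.3 (edgeR log2 difference -0.15), and Tcf7 had 0.92 but means of 83.5 ± 58.9 and 77.3 ± 50.1 (edgeR log2 difference -0.12). Cxcr5, the follicle homing receptor, was at 4.08 ± 5.52 and 0.468 ± 0.541 and not tested. Il21 and Cd40lg, products through which Tfh cells help B cells, had no reads in any library, and Il4 only 4 reads, all with IL-15. Opponents of the Tfh program had a median of 0.29 and a mean of -0.14 over 10 tested members (camera adjusted p = 0.953). Among them Il7r was at 48.1 ± 35.9 and 3.60 ± 5.99 (log2 difference -3.16). Naive and resting T cell genes had a median of 0.77 over 21 members (camera adjusted p = 0.855).

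**Figure D1:**
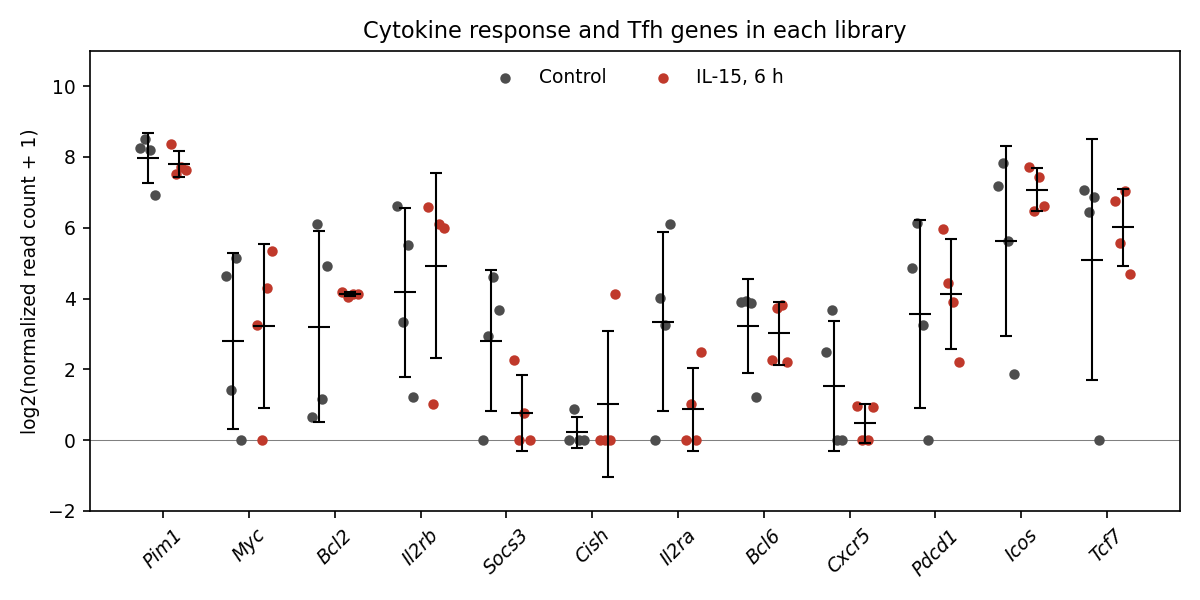
Log2(normalized read count + 1) of 12 cytokine response and Tfh genes in each library, with control libraries in grey and libraries cultured with IL-15 for 6 h in red. Points are single libraries and black bars the mean and SD of the 4 on this scale. The groups overlap for each gene, as for Pim1, whose log2 difference was -0.17.

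Cell cycle genes gave the group nearest to its threshold. Of 28 G2/M genes, 19 were tested, 13 below and 6 above 0, with a median log2 difference of -0.88. Cenpe, a centromere-associated kinesin, was at 221.6 ± 185.7 in controls and 31.5 ± 27.5 with IL-15 (log2 difference -2.87), Kif20a, a kinesin of cytokinesis, at 36.9 ± 18.5 and 5.26 ± 10.5 (log2 difference -3.95), and Birc5, which encodes survivin, at 52.1 ± 48.3 and 6.97 ± 10.1 (log2 difference -3.11). Mki67 was at 78.0 ± 38.5 and 49.5 ± 12.8 (log2 difference -0.49). Camera gave an unadjusted p of 0.00207 and an adjusted p of 0.0601, with adjusted p = 0.449 with an estimated correlation and adjusted p = 0.186 in fry. The summed G2/M count of each IL-15 library lay below that of each control (exact permutation p = 0.0286, the smallest possible, and 0.958 adjusted over the lists). With normalization by library totals alone, the group passed the camera threshold at the preset correlation (adjusted p = 0.0483) but not with an estimated one (adjusted p = 0.417), a setting chosen after seeing the data. The size of the difference depended on single libraries and on the filter: with 1 library left out, the median was -0.83 to -0.42 and the camera adjusted p 0.0633 to 0.450, and without the filter the median was -0.19 (camera adjusted p = 0.735). G1/S genes had a median of 0.39 over 15 tested members (camera adjusted p = 0.953), with Mcm3, of the replicative helicase, at 18.9 ± 22.1 and 76.8 ± 56.5 (log2 difference 3.09) and Ccnd3, a D-type cyclin, at 27.7 ± 23.5 and 2.93 ± 4.77 (log2 difference -2.96).

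**Figure D2:**
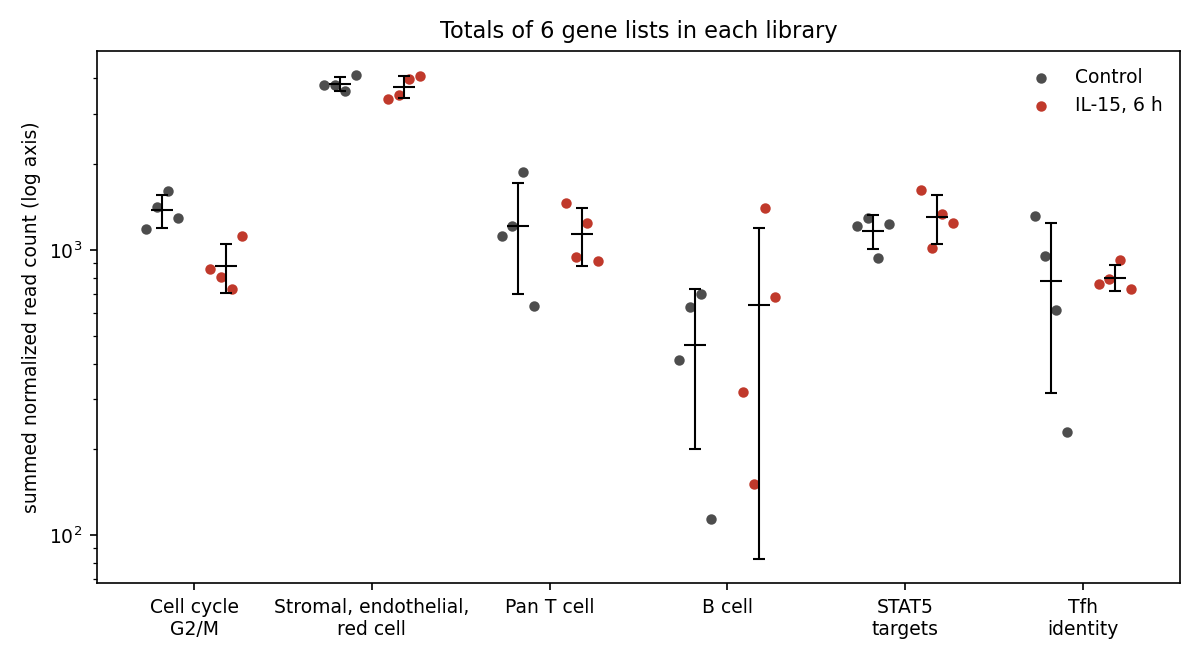
Summed normalized read counts (log axis) of 6 gene lists in each library, with control libraries in grey and IL-15 libraries in red. Points are single libraries and black bars the mean and SD of the 4. The G2/M totals averaged 1378 in controls and 878 with IL-15, and the stromal, endothelial and red cell total 3818 and 3741.

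Growth and metabolism genes did not pass the test as groups. MYC targets had a median of 0.03 over 35 members (camera adjusted p = 0.953), with Srm, which encodes spermidine synthase, at 12.3 ± 18.6 and 85.3 ± 72.0 (log2 difference 3.66) and Nop58, a small nucleolar ribonucleoprotein, at 101.4 ± 49.3 and 27.6 ± 19.0 (log2 difference -2.19). The 79 cytosolic ribosomal protein genes had a median of 0.04 (camera adjusted p = 0.559), with Rpl30 at 387.0 ± 180.5 and 717.5 ± 129.0 (log2 difference 1.00) and Rps13 at 203.7 ± 92.8 and 438.6 ± 250.6 (log2 difference 1.02). Both have processed pseudogenes that can share their reads. Glycolysis had a median of 0.15 over 14 members (camera adjusted p = 0.953), with Eno1, which encodes enolase, at 328.4 ± 46.1 and 172.4 ± 30.1 (log2 difference -0.93) and Pfkm at 6.05 ± 7.93 and 38.3 ± 23.3 (log2 difference 3.30). Nuclear encoded oxidative phosphorylation genes had a median of 0.13 over 46 members (camera adjusted p = 0.893), with Atp5po at 57.7 ± 51.8 and 129.2 ± 60.3 (log2 difference 1.35). All 13 mitochondrially encoded transcripts lay below 0, with a median of -0.15 (camera adjusted p = 0.116, and adjusted p = 0.953 with an estimated correlation). The nearest to the threshold were mt-Nd4, at 3901 ± 442 and 3292 ± 332 (log2 difference -0.24), and mt-Cytb, at 4686 ± 346 and 4222 ± 536 (log2 difference -0.16). Amino acid, one-carbon and ATF4 genes had a median of -0.35 over 21 members (camera adjusted p = 0.559), with Shmt2, the mitochondrial serine hydroxymethyltransferase, at 19.2 ± 16.9 and 88.0 ± 40.7 (log2 difference 2.59) and Atf4 at 230.4 ± 22.2 and 134.2 ± 67.7 (log2 difference -0.92). Cholesterol synthesis genes had 0.19 over 20 members (camera adjusted p = 0.953), with Sqle at -1.29 and Hmgcs1 at 1.43.

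Genes of the unfolded protein response had a median of 0.00 over 16 members, 8 above and 8 below 0 (camera adjusted p = 0.953). Adjusted over the list alone, 1 member was lower, Sel1l (adjusted p = 0.0089 in limma), and 0 were over all genes tested. It was the only such call among the 38 lists. Pdia3, a disulfide isomerase, was at 34.0 ± 24.7 and 124.1 ± 121.6 (log2 difference 1.63), or 64.4 with IL-15 when library 1 is left out. Heat shock genes had a median of -0.15 and a mean of 0.02 over 13 members (camera adjusted p = 0.953). Hspa8, the constitutive HSP70, was at 580.1 ± 191.1 and 1015 ± 305 (log2 difference 0.83), and Hsp90ab1 at 1275 ± 189 and 1596 ± 673 (log2 difference 0.25).

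Interferon, survival and signalling groups did not pass either. Type I interferon genes had a median of 0.10 over 7 members, with Rigi, a cytosolic RNA sensor, at -2.31. Interferon gamma genes had 0.13 over 13, with Gbp7 at -3.36 and Nlrc5, which drives class I antigen presentation genes, at -3.26. Both groups had a camera adjusted p of 0.953, as did the pro-survival genes, with a median of 0.47 and a mean of -0.14 over 8. Of these, Birc5, also a G2/M gene, had -3.11 and Bcl2a1b, from a family of near-identical copies, 1.65. Pro-apoptotic genes had -0.76 over 6 (camera adjusted p = 0.636) and totals of 318.5 ± 115.8 and 183.9 ± 28.3 (exact permutation p = 0.0571, and 0.958 adjusted over the lists). Among them the death receptor Fas was at -1.84 and Bcl2l11, which encodes BIM, at -1.42. The control mean of Fas was 44.5, and 19.2 without control 4, against 15.8 with IL-15. Immediate early genes had -0.45 over 17 (camera adjusted p = 0.559), with Dusp2 at -1.99 and Nfatc1 at -1.25. NF-kB targets had -0.61 over 12 and negative feedback genes 0.15 over 9, both with a camera adjusted p of 0.953. Their leading members were Nfkb1 at 1.08, Cblb, a ubiquitin ligase, at -1.47 and Dusp5 at -1.72. Co-inhibitory and co-stimulatory receptors had 0.56 over 7 (camera adjusted p = 0.648), and -0.11 without control 4, and chemokine receptors and trafficking genes 0.49 over 12 (camera adjusted p = 0.953), with the integrin Itgb1 at 1.02.

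Effector and helper lineage groups had fewer than 5 tested members each, so their totals were compared by exact permutation. Cytotoxic molecules summed to 248.9 ± 147.3 in controls and 417.0 ± 215.1 with IL-15 (exact p = 0.286). Most of both totals came from the only 2 tested of 23 members. These were Lamp1, a lysosomal membrane protein, at 68.1 ± 36.3 and 171.1 ± 63.5 (log2 difference 1.40) and Srgn at 146.8 ± 92.6 and 174.3 ± 154.5 (log2 difference 0.38). Gzmb was at 3.75 ± 7.51 and 2.87 ± 5.75, and Prf1, which encodes perforin, had no reads in any library. T helper 1 genes summed to 218.6 ± 167.6 and 193.4 ± 53.8 (exact p = 0.857), with Ifngr1 at -1.32, Stat4 at 1.40, Tbx21 at 0.331 ± 0.661 and 0.173 ± 0.347, and Ifng at 2.89 ± 5.78 and 0.975 ± 1.36. T helper 2 genes summed to 261.0 ± 105.2 and 391.6 ± 172.8 (exact p = 0.257), with Stat6 at 0.44 and Il1rl1 at 0.15. The counts of Il1rl1, 170.1 ± 82.2 and 192.3 ± 110.1, were a large part of this total and also enter the NK and innate lymphoid total. T helper 17 genes summed to 89.4 ± 71.1 and 55.1 ± 55.8 (exact p = 0.314; 54.7 in controls without control 3, and 28.1 with IL-15 without IL-15 library 1), with Ahr at -1.64 and Rora at -1.46. Regulatory T genes summed to 208.2 ± 61.0 and 182.6 ± 96.5 (exact p = 0.6), with Capg at 1.89 and Ikzf2 at -1.81. Foxp3 had 0 reads in controls and only 6 with IL-15, in 2 libraries (1.43 ± 1.77), and was not tested. T cell cytokines summed to 385.4 ± 127.7 and 425.3 ± 84.9 (exact p = 0.571), with Tnfsf8 at -0.68 and Csf1 at -0.18 but with means of 23.6 ± 9.03 and 35.6 ± 46.1 (edgeR log2 difference 0.60). Prdm1, which encodes BLIMP-1, had no reads in controls and only 5 with IL-15, all in library 3 (0.867 ± 1.73), and was not tested.

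Markers of T cells were present in every library. The 16 pan T cell markers summed to 1213 ± 510 in controls and 1141 ± 259 with IL-15 (exact permutation p = 0.971), with a median of 0.13 (camera adjusted p = 0.953). Trbc2, a T cell receptor constant segment, was at 245.0 ± 85.6 and 260.8 ± 117.1, Trac at 140.6 ± 108.1 and 106.7 ± 46.4, Cd3d at 84.6 ± 52.1 and 63.9 ± 41.2, Cd3e at 111.3 ± 166.1 and 81.9 ± 77.5, Thy1 at 122.6 ± 39.0 and 81.6 ± 35.1, Cd3g at 25.8 ± 51.0 and 54.0 ± 39.2, and Cd4 at 25.1 ± 17.4 and 42.2 ± 16.2. Stromal, endothelial and red cell markers summed to 3818 ± 211 and 3741 ± 343 (exact permutation p = 0.657, camera adjusted p = 0.953, median 0.09), above the T cell total in both groups. The fibrillar collagen genes Col1a2 and Col1a1 were at 1637 ± 492 and 1521 ± 88.3, and at 317.9 ± 46.1 and 283.9 ± 48.8. Sparc, a matrix protein, was at 826.4 ± 172.9 and 804.9 ± 342.6, and Dcn, which encodes decorin, at 100.04 ± 73.2 and 115.1 ± 55.8. The haemoglobin genes Hba-a2, Hbb-bs and Hba-a1 were at 443.3 ± 262.1 and 446.3 ± 112.4, 309.9 ± 177.2 and 392.2 ± 141.4, and 90.0 ± 73.2 and 100.2 ± 44.2, and near-identical copies can share their reads.

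B cell markers summed to 464.2 ± 264.3 and 640.7 ± 558.1 (camera adjusted p = 0.953, median 0.65). The light chain constant segment Igkc was at 290.8 ± 195.3 and 473.6 ± 594.0, Ighm at 56.3 ± 67.1 and 50.7 ± 84.5, H2-Eb1 at 14.2 ± 22.9 and 31.3 ± 38.9, and Cd74 at 21.8 ± 15.6 and 14.1 ± 20.2. Without IL-15 library 1, H2-Eb1 was at 12.3 with IL-15. Germinal centre B and plasma cell markers summed to 236.3 ± 71.0 and 390.0 ± 333.0 (camera adjusted p = 0.648, median 1.14), with Igha at 86.9 ± 65.7 and 254.5 ± 280.1 and Xbp1 at 16.4 ± 17.9 and 36.1 ± 15.2. The higher IL-15 means of both totals, Igkc and Igha rested largely on IL-15 library 3: without it they were 385.0 for the B cell total, 185.9 for Igkc and 227.8 for the germinal centre B and plasma cell total, each below the control mean, and 119.0 for Igha. Myeloid and dendritic cell markers summed to 478.4 ± 69.4 and 521.4 ± 179.2 (exact permutation p = 0.886), of which Cst3, which encodes cystatin C, was 365.5 ± 65.3 and 381.5 ± 141.1, Ifi30 24.6 ± 23.9 and 13.7 ± 18.2, and Lyz2 15.1 ± 15.2 and 33.3 ± 33.9. NK and innate lymphoid markers summed to 188.8 ± 61.6 and 205.4 ± 104.3 (exact permutation p = 0.914), and CD8 T cell markers to 10.2 ± 14.5 and 10.1 ± 17.8 (exact permutation p = 1). Most of the NK and innate lymphoid total was Il1rl1, at 170.1 ± 82.2 and 192.3 ± 110.1, which is also in the T helper 2 group.

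The spread between libraries limited what could be called. Control 4 weighed most on the direction of group medians: of 22 tested groups with a median above 0, 17 had one below 0 without it, among them the STAT5 group at -0.37 and the pan T cell markers at -0.38. Control 3 weighed most on the direction of group totals, of which 11 turned without it and 5 without control 4. The median SD within groups was 0.33 on the log2 scale for 133 genes with a mean over 500, and 1.82 for 5088 genes with a mean of 10 to 100. In simulated comparisons of these 2 groups over 6180 genes, limma recovered 2% of genes changed 4-fold and 30% of those changed 16-fold, and 40% and 93.9% among genes with a mean of 500 or more. A log2 shift of 1 in the STAT5 or Tfh group was called by camera at the preset correlation in 3 of 10 runs and a shift of 2 in 10 of 10. The simulated genes were drawn independently of each other. In the data the estimated correlation was 0.28 in the Tfh group and -0.02 in the STAT5 group, so recovery for the Tfh group may be overstated.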

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

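In 40 of 286 groups of 4 libraries, 1 library lay far from the other 3 in a gene named in the report, a list total or a library measure. Chance gives about 1 in 20 for normally distributed values, but 11 of the 40 were groups with reads in 1 library only, which meet the measure by construction, so the number is not compared with chance. Each library held 2 to 8 of them. No explanation was tested. Values are normalized counts against the range of the other 3 libraries of the group.

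Control 1 had Furin 44.5 against 15.8 to 17.2, Pik3r1 392.8 against 31.7 to 71.7 and Rigi 100.5 against 10.6 to 11.1. It also had Cblb 24.3 against 63.5 to 70.9, Cd3g 102.2 against 0 to 0.834 and Ifng 11.6 against 0. Control 2 had Maf 41.7 against 0 to 2.31, Cish 0.834 against 0 and Gzmb 15.0 against 0. Control 3 had Gbp7 7.39 against 33.5 to 36.7, Birc5 124.4 against 24.2 to 33.5, Cd3e 359.6 against 11.9 to 44.5 and Usp32 433.5 against 98.2 to 128.5. It also had the sum of Opponents of the T follicular helper program 742.7 against 314.2 to 357.9 and the sum of Pro-survival BCL2 family and relatives 513.6 against 301.0 to 327.8. Control 4 had Bcl6 1.32 against 13.5 to 14.2 and Tbx21 1.32 against 0. IL-15 library 1 had Furin 34.5 against 0 to 1.83, Rora 113.9 against 2.08 to 9.25, Gbp7 33.5 against 0 and Birc5 22.0 against 1.03 to 2.74. It also had Gzmb 11.49 against 0, Trbc2 435.6 against 189.3 to 216.8 and Smarca5 14.4 against 43.2 to 45.7. IL-15 library 2 had Bcl2a1b 94.6 against 36.8 to 39.3 and Col1a1 356.8 against 253.2 to 265.2. IL-15 library 3 had Il6ra 52.7 against 2.87 to 9.15, Il7r 12.5 against 0 to 1.92, Atp5po 39.5 against 148.2 to 168.5 and Nlrc5 66.6 against 0 to 0.915. It also had Il4 2.77 against 0, Prdm1 3.47 against 0, Tbx21 0.694 against 0 and the sum of CD8 T cell markers 36.8 against 0 to 2.74. IL-15 library 4 had Ccnd3 10.1 against 0 to 0.957, Kif20a 21.04 against 0, Rigi 83.2 against 0 to 0.957 and Cish 16.5 against 0. It also had Ighm 176.5 against 0 to 23.6 and Trac 37.5 against 124.8 to 136.0.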

How the results depend on the processing

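The counts of 0 genes and 0 lists in each direction held under TMM and upper-quartile factors, pseudocounts of 0.5 and 10 and array weights. Those of genes also held under voom and edgeR, where lists were not tested. Of these and the list tests, the pseudocounts, array weights and the permutation of list totals were chosen after seeing the data. EdgeR with TMM had been planned for deposited counts, and its use on recovered reads was chosen after seeing the data. Exceptions were these, and the cause was not tested. DESeq2 called 13 genes higher and 10 lower. Without a filter, 1 gene was higher (Marchf7) and 2 lower (Sel1l, Klf13). With library totals alone, 1 list was higher (cytosolic ribosomal proteins) and 1 lower (Cell cycle G2/M genes). With 1 library left out, 0 to 3 genes were higher, 0 to 4 lower, and 0 to 1 lists higher. The calls came without IL-15 library 2 (3 higher, Hook3, Ube2l3 and Crebrf; 4 lower, Usp32, Sel1l, Dhx30 and Usp42), IL-15 library 3 (1 higher, Marchf7; 1 lower, Tln1), IL-15 library 1 (1 lower, Klf13), control 1 (1 lower, Sel1l) and control 2 (1 higher, Akap9), and the list, ribosomal proteins, without control 3. With an estimated correlation in these 2 settings, combinations chosen after seeing the data, 0 lists were called. With the replicate number as a block, 0 genes and 0 lists were called; the numbers did not pair the samples, since same-numbered libraries correlated at -0.00475 to 0.00788 in their deviations from the group means. Of 106 named genes and 29 lists, 71 kept the sign of their log2 difference and 10 the direction given by the list test under all alternatives that gave them a value, while the median of 7 lists kept its sign; 72 of the genes and 16 of 38 list totals kept the direction of their mean difference with any 1 library left out. Depth and spread limit the test: simulated 2-fold changes were recovered in 0% of all tested genes and 4.71% of genes with a mean of 500 or more.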

Other observations

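All the tests in this part were chosen after the results they address were seen. The criteria for abundance and T cell transcription in the fibroblast transcripts, for chance and a single library in the G2/M list and for counts of 0 were revised after a first result, each time towards leaving the explanation open. The criterion for fibroblast RNA in the G2/M list went from excluded to open and back, and that explanation is left open below. Transcripts typical of fibroblasts, 39 listed after their levels were noticed, were abundant in all 8 libraries. Their summed normalized count was 9419 ± 2006 in controls and 8841 ± 726 with IL-15 (exact permutation p = 0.857), which was 4.23 to 19.3 times the pan T cell total of the same library and 1.31% to 2.04% of reads outside ribosomal RNA. Mean counts over the 8 libraries were 1579 for Col1a2, 992.6 for Meg3, 815.7 for Sparc, 752.1 for Lox, which encodes the collagen cross-linking lysyl oxidase, and 711.3 for Bgn, which encodes biglycan. Col3a1 and Lum, also fibroblast genes, were at 0.274 and 0.144.

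Whether these transcripts were even between libraries beyond what their abundance gives stays open. Their coefficient of variation had a median percentile of 35 among 200 genes of like abundance (bootstrap 95% interval 16 to 51, single genes 0 to 91.5). For abundance alone, 35 to 65 was set. The pan T cell markers were at 30.5 (permutation p of the difference = 0.614). The presence of the transcripts stays open too: their log2 total varied less than that of the pan T cell markers (exact p = 0.0195), but less abundant genes vary more, so this does not exclude transcription by the sorted T cells. A fibroblast-like source of RNA in every library is a candidate explanation, with 32 of the 39 genes read in all 8 libraries. Of the 39, 5 are in the stromal list and 1 in another list. The near absence of Col3a1 goes against it. The cells were sorted before culture, and no value here shows what the sort removed or what entered later. The fibroblast total tended to be lower where the pan T cell total was higher. In controls 1 to 4 the fibroblast totals were 8216, 9215, 7931 and 12313, and the pan T cell totals 1121, 1216, 1876 and 637. In IL-15 libraries 1 to 4 they were 8180, 9586, 8257 and 9340, and 1457, 943, 1246 and 916. These values argue against T cells making both in a fixed proportion, but the relation was not tested. The source stays open, because no library without T cells was analysed here.

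The lower G2/M counts with IL-15 had the smallest camera p of the 29 lists, and chance is not excluded once that choice is counted. In 13 of 35 splits of the libraries, the real one included, some list had a p as small as 0.00207, the smallest elsewhere being 2.76e-05, while for the G2/M list itself the real split was the only 1 of 35. A single library as part of the cause stays open: the unadjusted camera p was at most 0.0367 with 1 left out, but the median log2 difference shrank to as little as -0.42 and the adjusted p reached 0.450. For less fibroblast RNA with IL-15 as the whole cause, the criterion set against it was met, but the question stays open. The log2 fibroblast total differed by -0.0725 (95% interval -0.59 to 0.27, SD over the libraries 0.21) against -0.66 for the G2/M total. That interval lay above -0.66, but the G2/M difference had a 95% interval of -1.14 to -0.09, which overlaps it. The log2 ratio of these totals, which carries the spread of both, had an exact permutation p of 0.0857. An effect of IL-15 may contribute as well and was not separated from these.

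For the counts of calls, the split test says nothing about limma and camera, because any split reaches a count of 0 (35 of 35 for genes and 35 of 35 for lists; the highest other split gave 4 genes and 2 lists). The 261 genes at an unadjusted p under 0.05 were reached or exceeded in 33 of 35 splits. The 23 genes of DESeq2 were reached or exceeded in 14 of 35 splits, and the highest other split gave 43, so a split unrelated to IL-15 called more.

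Certain read numbers were over-represented at even spacing in the histograms of recovered reads. A candidate explanation is read numbers scaled by 1 factor per library and rounded before the size factors were applied. With 1 best factor under 1 per library, 6 of 8 libraries lay beyond 95% of 200 smooth simulated histograms, and control 1 and IL-15 library 3 did not. The test does not decide, and recovered reads may thus differ from the original read numbers.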
